A study of Mus musculus with 6 samples.

How the data were processed

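Polyadenylated RNA of mouse tail-tip skin cells was sequenced in 6 libraries, 2 for each of 3 groups. Per the labels, fibroblasts received control lentiviral vectors and stand for day 0, early cells received CRISPR activation vectors and stand for day 7, and late cells received CRISPR activation vectors, were isolated as colonies and stand for day 22. CRISPR activation uses a Cas9 without cutting activity to bring transcriptional activators to a promoter. The labels name the SAM version of the system, and the targeted genes are not given in the sources used here. RNA was purified with a PureLink kit and cDNA was made with poly(A) selection, per the labels' protocols.

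The authors deposited a table of raw read counts per Ensembl gene, not normalized, for all 6 libraries. The strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 with the genome build GRCm38 are named in the submitters' processing notes. Genes with near-identical copies, such as the histone and alpha-globin genes, and genes overlapped by antisense transcripts, as in the Hox clusters, therefore carry uncertain counts. Of the mitochondrial genome, mt-Co2 stayed at or below 6.94 CPM and mt-Co3 at or below 8.99 CPM, while mt-Co1 was the most abundant transcript of early replicate 2 and late replicate 2. Parts of that genome have near-identical copies in the nucleus, so values of single mitochondrial transcripts are uncertain.

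The columns of the fibroblast libraries carry their sample titles. The columns of the early and late libraries were assigned by name, because their names are not exact sample titles: the abbreviation for induced cardiac progenitors was taken as the late group, and the abbreviation for fibroblasts with an added letter c as the early group. The order of columns and the values were not used. If that reading were wrong, the early and late values would change places. The labels describe early replicate 1 as early and early replicate 2 as partially reprogrammed; both were treated as the same group. Replicate numbers were taken from the labels, which do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries. Xist had 1625 against 4 counts in the fibroblast libraries and 1468 against 12 in the late ones, and C3 was at 62.7 and 4034 CPM in the early ones, too far apart for repeats of the same RNA sample. Part of the spread may still be technical.

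The table lists 49315 genes, of which 31952 had a count in at least 1 library. Symbols and positions came from GENCODE release M21 on GRCm38; 48970 identifiers had a symbol and 345 had none. Total counts ranged from 20172874 to 40122999 per library. A count of 3, taken as the floor, corresponded to between 0.0748 and 0.149 CPM. A fold against a group without counts is given as a lower bound computed with 3 counts over that group, and a fold against 1 to 3 counts is given as a ratio with an exact 95% interval. Such intervals and floors cover counting error only.

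Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the default expression filter (16688 genes), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to the means of the 3 groups over all 6 libraries without a block, leaving 3 residual degrees of freedom. The 3 pairwise contrasts were tested with Benjamini-Hochberg adjustment, and a gene is said to have risen or fallen at an adjusted p under 0.05. The common biological coefficient of variation was 48.6%. Standard errors were derived from the fold change and the F statistic. Values per library are CPM, counts scaled to a common effective library size after TMM.

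Each of 31 gene lists with at least 3 tested members was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list ranks apart from the other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in the same direction, were alternatives. The lists, the design and all but 2 of the alternatives were fixed before the data were examined. Among 737 listed symbols, 4 were not matched. Named genes were chosen by a rule fixed with them. It took the 8 largest rises and 8 largest falls among called genes with a mean over the 6 libraries of their log2 CPM of at least 3, no overlap between the libraries of the groups and a symbol that is not a predicted gene name. It also took Gata4, Nkx2-5, Tbx5, Mef2c, Hand2 and Isl1 whatever their test, the 4 members of each list with the smallest adjusted p, and any further member of a list with 5 or fewer called genes. List members without counts in a whole group could be named as such. Xist was chosen after its values were seen. Some genes that the rule names are not reported here.

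The tests were tried on simulated counts for the 16688 genes with the dispersions and library sizes of these data and 200 changed genes. For early against fibroblast, 6 of 67 genes changed 4-fold, 47 of 67 changed 16-fold and 57 of 66 changed 64-fold were called in the right direction, with 6 unchanged genes called. For late against fibroblast the numbers were 9 of 67, 56 of 67 and 55 of 66, with 12 unchanged genes called. For late against early they were 18 of 67, 56 of 67 and 62 of 66, with 15 unchanged genes called. Among 200 random lists of unchanged genes camera gave an unadjusted p under 0.05 for 2.5%, 1.5% and 2.5% in these 3 comparisons, in the same order. The simulated genes varied independently of each other. These shares therefore do not tell how often camera calls an unchanged list whose genes vary together.

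Alternatives were DESeq2 size factors, scaling by total count, the Wald test of DESeq2 1.42.0 on all genes with a count and its own independent filtering, limma-voom, no filter, a stricter filter (at least 1 CPM in 2 libraries and 50 counts in total), the replicate number as a block, only the libraries of the compared groups, an adjusted p under 0.01, a test against a 1.5-fold change, and leaving out each library in turn. Leaving out the transcripts of the mitochondrial genome, and the Wald test of DESeq2 on the 16688 genes kept by the filter, were added after the data were seen. Where a library is left out, the remaining library of its group is assumed to vary like the others.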

Results

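RNA sequencing compared mouse tail-tip fibroblasts with cells at 2 stages of reprogramming by CRISPR activation, which switches on genes at their own promoters with a Cas9 that does not cut. The 6 libraries comprised 2 of control fibroblasts (day 0), 2 of early reprogrammed cells (day 7) and 2 of late cells, described as induced cardiac progenitors and taken from isolated colonies (day 22). The assignment of the early and late columns rests on their names. Total counts were 31414965 and 37445443 for the fibroblast libraries, 21273130 and 20469433 for early, and 20172874 and 40122999 for late. The libraries of a group correlated across genes at r = 0.978 for fibroblast, 0.939 for early and 0.883 for late (Pearson, log2 CPM; genes are not independent replicates). Early replicate 1 and late replicate 1 correlated at 0.945, above the correlation within either of their groups. Between the 2 libraries of a group, 450 genes differed more than 4-fold in fibroblasts, 1316 in early and 1958 in late cells. Late replicate 2 stood apart on the second principal component, and its transcripts of the mitochondrial genome made up 10.3% of counts against 1.48% to 2.16% in the other 5 libraries. Xist, the RNA of the inactive X chromosome, was at 54.6 CPM in fibroblast replicate 1 and 61.2 CPM in late replicate 1 and at or below 0.337 CPM in the other 4 libraries, while genes of the Y chromosome had counts in all 6. Neither early library thus held Xist at the level of late replicate 1, and the libraries may come from different animals or cultures. Differences between stages cannot be separated from such differences.

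**Figure D1:**
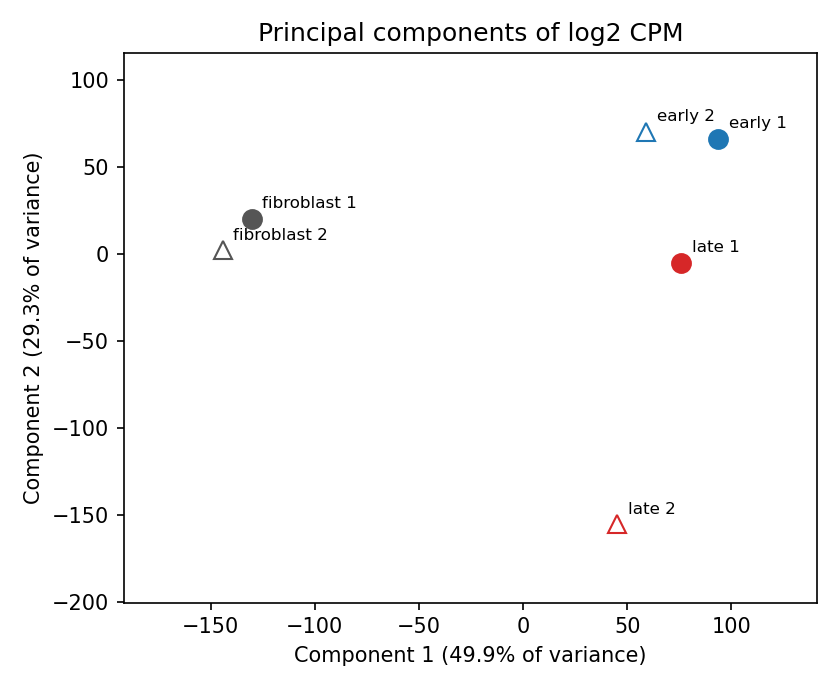
First and second principal components (axis units are log2 CPM scores) of the 16688 tested genes, with each point a library, colour for the group and filled circles for replicate 1 and open triangles for replicate 2. The fibroblast libraries lie at -130 and -144 on the first component, which holds 49.9% of variance, and late replicate 2 lies at -155 on the second, which holds 29.3%.

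The comparison of early cells with control fibroblasts asks what differed between the day 7 libraries and the fibroblast libraries. Several transcription factors of heart development were higher in early cells, with 17 of 27 measured members of the list above fibroblasts and 10 below. Gata6, a zinc-finger factor of heart and endoderm development (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635 in GRCm38), was at 66.1 and 165 CPM in early libraries against 0.739 and 0.853 in fibroblasts, a log2 fold change of 7.17 ± 0.59 (SE, edgeR adjusted p = 0.0221). Gata4, a related factor required for heart formation (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692), was at 19.8 and 17.8 CPM against 0.168 and 0.324, a log2 fold change of 6.22 ± 0.66 (adjusted p = 0.0339). Zfpm2, a cofactor of GATA factors, rose by 2.17 ± 0.21 on the log2 scale (adjusted p = 0.0282), and Tbx2, a T-box repressor, by 3.77 ± 0.41 (adjusted p = 0.0351). Of the 27 heart transcription factors, 4 rose and 0 fell over all genes tested, and adjusted over the list alone 10 rose and 3 fell. The list ranked higher than other genes (camera adjusted p = 0.0151, and adjusted p = 0.821 with an estimated correlation). It missed the threshold without fibroblast replicate 1 (0.0572) or late replicate 1 (0.0597). Gene calls of this comparison were also lost when a fibroblast or early library was left out. Such a fit keeps 1 library of that group, so a lost call does not show that it rested on the library left out. Of 38 called genes followed one by one, 38 missed the threshold without fibroblast replicate 1 (edgeR adjusted p from 0.164 to 0.265) and 38 without fibroblast replicate 2 (0.160 to 0.308). The number was 36 without early replicate 1 (0.0523 to 0.168) and 14 without early replicate 2 (0.0541 to 0.108).

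Several heart factors had higher values in both early libraries without passing the test. Hand2, a factor of ventricle formation, was at 18.0 and 128 CPM against 1.38 and 1.41 (log2 fold change 5.70 ± 1.03, adjusted p = 0.0603). Isl1, a marker of second heart field progenitors, was at 16.4 and 9.70 CPM against 0.101 and 0.0294 (7.58 ± 1.44, adjusted p = 0.0640). Nkx2-5, a homeobox factor of early heart cells, was at 6.46 and 1.75 CPM against 0.0336 and 0.147 (5.41 ± 1.58, adjusted p = 0.102). Tbx5 had 3 counts over both fibroblast libraries and was at 11.9 and 3.55 CPM in early libraries, a ratio of 167 with an exact 95% counting interval of 56.8 to 815 (edgeR adjusted p = 0.0712). Tbx20 was at 43.9 and 6.20 CPM against 0.839 and 1.29 (log2 fold change 4.54, adjusted p = 0.0728). Mef2c was at 8.11 and 23.3 CPM against 14.3 and 22.7 (log2 fold change -0.24 ± 0.78, adjusted p = 0.866). Cardiovascular progenitor and early mesoderm markers as a list ranked higher, with 14 of 24 above fibroblasts and 1 called, Osr1, a factor of the early mesoderm (adjusted over the list alone, 10 rose and 2 fell, camera adjusted p = 0.0459, and 0.821 as adjusted p with an estimated correlation). Summed over all 30 listed genes, CPM was 486 and 1352 in early libraries against 1506 and 1211 in fibroblasts. That list missed the threshold without fibroblast replicate 1 (0.0649) or early replicate 2 (0.232).

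**Figure D2:**
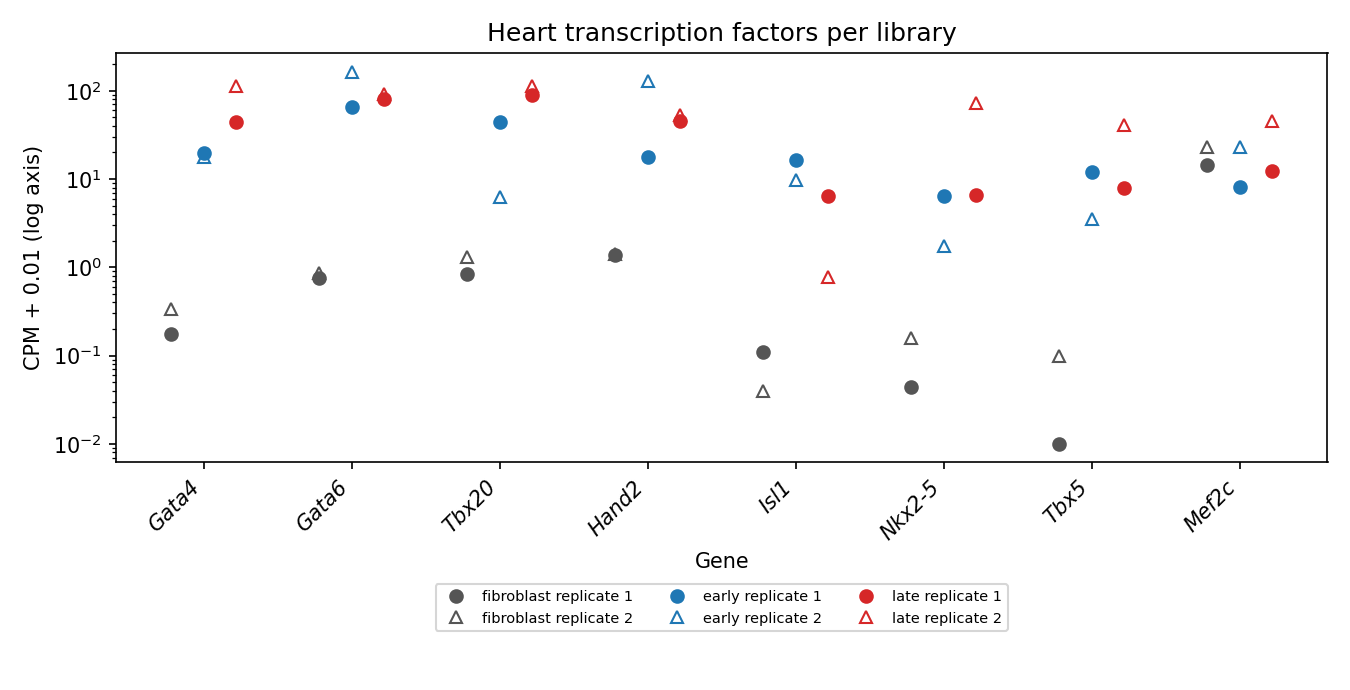
CPM of 8 heart transcription factors in each library on a log axis after adding 0.01, with colour for the group, filled circles for replicate 1 and open triangles for replicate 2. Gata4 lies at 19.8 and 17.8 CPM in early and 44.2 and 113 CPM in late libraries, and at or below 0.324 CPM in fibroblasts, while Mef2c overlaps between the groups.

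Hox genes, which mark position along the body axis, differed in opposite directions by position, and the counting could not separate them from antisense transcripts if strand was ignored. Hoxb13, a gene of the tail end of the body (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447), was at 66.3 and 79.1 CPM in fibroblasts and had 3 counts over both early libraries, so fibroblasts were higher by a ratio of 1062 (exact 95% counting interval 363 to 5153, edgeR adjusted p = 0.0198). Hoxc12 was at 99.2 and 109 CPM in fibroblasts against 3 counts in early cells, a ratio of 1514 (interval 518 to 7346, edgeR adjusted p = 0.0332). Hoxa13 fell by 6.22 and Hoxc13 fell by 5.38 on the log2 scale (edgeR adjusted p = 0.0412 and 0.0480). Of 15 measured posterior Hox genes, 4 fell and 0 rose, and 8 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00849, and adjusted p = 0.892 with an estimated correlation). Of 20 anterior and middle Hox genes, Hoxa2, Hoxa3 and Hoxa4 rose, by 5.66, 4.90 and 4.85 on the log2 scale, and 5 rose adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.863 with an estimated correlation).

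**Figure D3:**
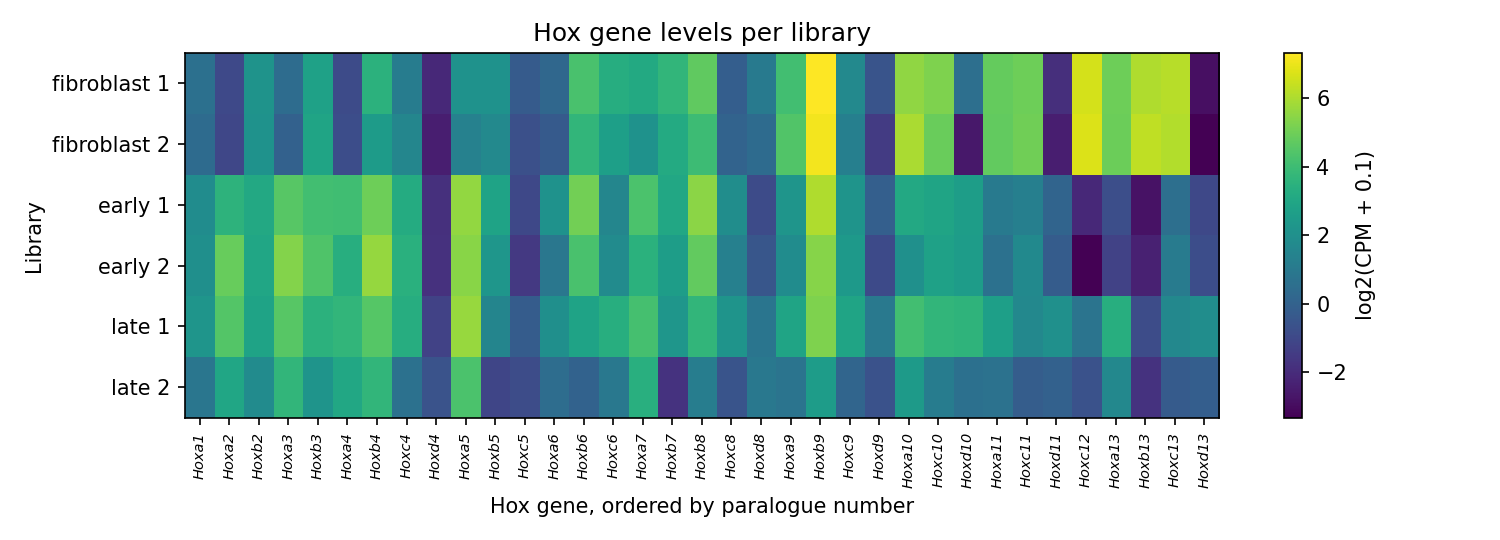
Heat map of log2(CPM + 0.1) for the tested Hox genes, with columns ordered by paralogue number and rows for the 6 libraries. Hoxb13 goes from 66.3 and 79.1 CPM in fibroblasts to at most 0.459 CPM in the other libraries, while Hoxa3 goes from 1.28 and 0.882 CPM to between 12.7 and 40.8 CPM.

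Proliferation genes stood higher in early cells and cell cycle inhibitors lower. Of 35 cell cycle and DNA replication genes, 34 were higher and 0 passed the test over all genes, while 32 rose adjusted over the list alone (median log2 fold change 3.65, camera adjusted p = 1.68e-09, and 0.821 as adjusted p with an estimated correlation). Top2a, a topoisomerase of dividing cells, was at 613 and 124 CPM against 22.6 and 15.9, and Mki67 at 432 and 61.6 CPM against 11.8 and 9.97. Of 20 p53 target and inhibitor genes, 17 were lower and 1 fell, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00190, and adjusted p = 0.821 with an estimated correlation). That called gene was Cdkn1a, the p21 inhibitor (622 and 609 CPM in fibroblasts, 148 and 127 in early cells, edgeR adjusted p = 0.0484). Cdkn2a, which encodes p16 and p19ARF, was at 569 and 568 CPM against 44.4 and 104 without passing the test (adjusted p = 0.0724).

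Fibroblast and matrix genes and smooth muscle genes ranked lower as lists. Of 40 fibroblast and extracellular matrix genes, 25 were lower. S100a4 fell (log2 fold change -3.07 ± 0.39, edgeR adjusted p = 0.0415) while Col14a1 rose (6.09 ± 0.48, adjusted p = 0.0221), and 3 fell and 1 rose adjusted over the list alone. The list ranked lower (camera adjusted p = 0.0146, and adjusted p = 0.892 with an estimated correlation), but its direction turned without early replicate 1 (adjusted p = 0.981). Smooth muscle genes ranked lower too, with 20 of 25 below fibroblasts. Itga8 fell, Rgs5 rose, and 16 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00177, and adjusted p = 0.821 with an estimated correlation). The sarcomere list was not called (5 members higher and 24 lower, camera adjusted p = 0.533), but ranked lower without late replicate 1 (0.0160) or late replicate 2 (0.0306). Summed over the 32 listed sarcomere genes, CPM was 107 and 322 in fibroblasts and 172 and 216 in early libraries. Reads of late replicate 2 carried into fibroblast replicate 2 could raise its values, and were not separated. Macrophage and leukocyte markers were lower for 19 of 20 members, with 0 called over all genes and 15 that fell adjusted over the list alone (camera adjusted p = 3.63e-05, and adjusted p = 0.821 with an estimated correlation). Lyz2, a lysozyme of macrophages, was at 181 and 787 CPM in fibroblasts and 1.02 and 7.29 CPM in early cells. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, were lower for 12 of 13 members, with 0 called and 7 that fell adjusted over the list alone (camera adjusted p = 0.000101, and adjusted p = 0.821 with an estimated correlation). After poly(A) selection, their counts in every comparison also depend on how much RNA without a tail passed the selection.

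Interferon-stimulated genes were higher for 27 of 32 members, with 0 called over all genes and 10 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.000262, and adjusted p = 0.821 with an estimated correlation). Chromatin genes were higher for 19 of 26, with 0 called and 1 that rose adjusted over the list alone (camera adjusted p = 0.0139, and adjusted p = 0.821 with an estimated correlation), and missed the threshold without early replicate 1 (0.0542). Among called genes under the rule for named genes, large rises were those of Podxl, a sialomucin of the cell surface (log2 fold change 7.81 ± 0.75), Prdm6 (7.53 ± 0.48), Ildr2 (7.20 ± 0.31), Gata6, Frmd5 (7.16 ± 0.79), and Hp and Lcn2, both acute-phase proteins (7.11 ± 0.72 and 6.73 ± 0.54). The rule's limit on mean expression leaves out Hoxb13 and Hoxc12, which fell further. Large falls under it were those of Igfbp5, a binding protein of insulin-like growth factors (-7.91 ± 0.88), Htr1b, a serotonin receptor (-7.56 ± 0.61), Itga8 (-7.44 ± 0.66), Sfrp2, a Wnt modulator (-7.36 ± 0.84), Tmem47 (-7.06 ± 0.90), Coch (-7.03 ± 0.68), Hmcn1 (-6.80 ± 0.75) and Mfap3l (-6.40 ± 0.43). Their edgeR adjusted p lay between 0.0139 and 0.0423.

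In all, 255 of 16688 genes were called between early cells and fibroblasts by edgeR, 116 higher and 139 lower, with 4976 at an unadjusted p under 0.05. Without fibroblast replicate 1 or fibroblast replicate 2 the count was 0 (2675 and 2272 at an unadjusted p under 0.05), and without early replicate 1, early replicate 2, late replicate 1 or late replicate 2 it was 6, 546, 661 or 823. The balance of directions moved with the early libraries, to 6 higher and 0 lower without early replicate 1 and 411 higher and 135 lower without early replicate 2. All 255 kept their direction in each of these fits.

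The comparison of late cells with control fibroblasts asks what distinguishes the libraries of induced progenitors from the fibroblast libraries. Gata4 was at 44.2 and 113 CPM in late libraries, a log2 fold change of 8.28 ± 0.71 over fibroblasts (edgeR adjusted p = 0.0311), and Gata6 at 80.8 and 92.7 CPM, a change of 6.76 ± 0.58 (adjusted p = 0.0311). Tbx2 rose by 4.86 ± 0.43, Zfpm2 by 1.94 ± 0.21, and Hand1, a factor of the heart and extraembryonic mesoderm, by 7.39 ± 1.02 on the log2 scale (adjusted p = 0.0317, 0.0364 and 0.0485). Of 27 heart transcription factors 5 rose and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 1.95e-05, and adjusted p = 0.649 with an estimated correlation). Of 39 called genes followed one by one, 39 missed the threshold without fibroblast replicate 1 (edgeR adjusted p from 0.226 to 0.290), 39 without fibroblast replicate 2 (0.190 to 0.309) and 35 without late replicate 2 (0.0537 to 0.0907). The number was 7 without early replicate 1 (0.0501 to 0.0546), 5 without early replicate 2 (0.0504 to 0.0514) and 3 without late replicate 1 (0.0520 to 0.0553). Tbx20 at 89.9 and 114 CPM (adjusted p = 0.0564), Nkx2-5 at 6.50 and 71.9 CPM (0.0654) and Isl1 at 6.34 and 0.758 CPM (0.0760) did not pass. Hand2 had a log2 fold change of 5.12 (0.0645) and Mef2c of 0.63 ± 0.78 (0.592). Tbx5 stood at a ratio of 594 (exact 95% counting interval 203 to 2885) over the 3 fibroblast counts, with an edgeR adjusted p of 0.0601. Progenitor and mesoderm markers were higher for 18 of 24 members, with Osr1 the 1 called and 14 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.00263, and adjusted p = 0.649 with an estimated correlation). Summed over all 30 listed genes, CPM went the other way, from 1506 and 1211 in fibroblasts to 590 and 703 in late libraries.

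Genes of the heart muscle contractile apparatus differed widely between the late libraries. Myh6, the myosin heavy chain of the adult mouse heart, was at 25.8 CPM in late replicate 1 and 25360 CPM in late replicate 2, against 7.82 and 62.8 CPM in fibroblasts. Actc1, cardiac actin, was at 16.2 and 6843 CPM, Tnnt2 at 15.1 and 5866 CPM, Ttn at 4.29 and 3095 CPM and Tnni3, cardiac troponin I, at 3.54 and 2129 CPM. All 29 sarcomere genes had a fitted value above fibroblasts, but only 6 had both late libraries above both fibroblast libraries, and 0 passed the test, also adjusted over the list alone. Reads of late replicate 2 carried into fibroblast replicate 2 could raise the fibroblast values, and were not separated. The list ranked higher (camera adjusted p = 0.00161, and adjusted p = 0.786 with an estimated correlation), and its adjusted p was 0.671 without late replicate 2. Genes of other cell types were also higher in that library. Hbb-bs, adult beta globin, was at 572 CPM against 0.667 in late replicate 1, Pecam1, an endothelial adhesion molecule, at 129 against 1.38, Adipoq, the fat cell hormone adiponectin, at 9.04 against 0.0417, and Lyz2, a lysozyme of macrophages, at 49.9 against 1.29. Summed over the leukocyte list, CPM was 316 in late replicate 2 and 76.2 in late replicate 1. Both lay below the 351 and 1432 CPM of the fibroblast libraries.

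**Figure D4:**
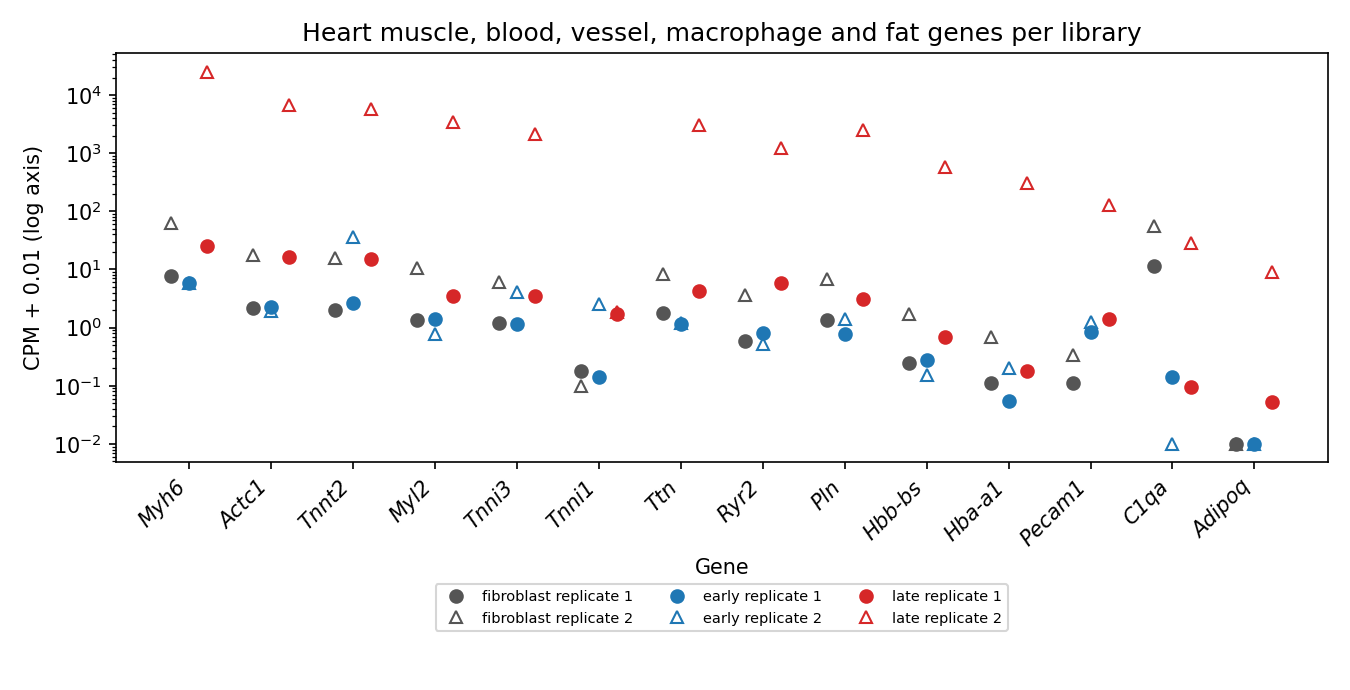
CPM per library, on a log axis after adding 0.01, of heart muscle genes (Myh6 to Pln) and of globin, endothelial, macrophage and fat cell genes, with colour for the group, filled circles for replicate 1 and open triangles for replicate 2. Myh6 reaches 25360 CPM in late replicate 2 and 62.8 CPM or less in the other 5 libraries, and Tnni1 is at 1.85 CPM in late replicate 2.

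Endothelial genes were higher for 15 of 17 members, with 0 called and 7 rising adjusted over the list alone (camera adjusted p = 0.0190, and adjusted p = 0.786 with an estimated correlation, or 0.204 at the preset correlation without late replicate 2). Kdr, a receptor of vascular growth factor, was at 10.4 and 170 CPM and Cdh5 at 8.71 and 174 CPM. Respiratory chain genes encoded in the nucleus were higher for 32 of 33 with 0 called, also over the list alone (camera adjusted p = 0.0238, and adjusted p = 0.798 with an estimated correlation), and mitochondrially encoded transcripts for 13 of 13 with 0 called (0.0333, and adjusted p = 0.798 with an estimated correlation). Both of these lists turned direction without late replicate 2 (adjusted p = 0.109 and 0.480) and missed the threshold without fibroblast replicate 1 (0.0738 and 0.0520), early replicate 1 (0.0534 for both) or early replicate 2 (0.0559 for both). Mcam, an adhesion molecule of vessel wall cells, was high in both late libraries (69.9 and 76.6 CPM against 2.12 and 1.32; log2 fold change 5.41 ± 0.36, edgeR adjusted p = 0.0294). Smooth muscle genes as a list were not called (adjusted p = 0.507), although Mcam and Rgs5 rose.

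Some epithelial genes rose in late cells, and the pluripotency genes ranked higher as a list without a called member. Krt8, a keratin of simple epithelia, was at 156 and 46.3 CPM against 0.436 and 0.294 (log2 fold change 8.10 ± 0.81, edgeR adjusted p = 0.0349), and Krt19 rose by 6.11 ± 0.81 (0.0471). Cdh1, E-cadherin, rose from 2 fibroblast counts to 20.1 and 6.60 CPM, a ratio of 384 (exact 95% counting interval 106 to 3174, edgeR adjusted p = 0.0468). Of 16 keratinocyte and epithelial genes 2 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 8.82e-05, and adjusted p = 0.660 with an estimated correlation). Of 11 pluripotency genes 9 were higher with 0 called, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00717, and adjusted p = 0.660 with an estimated correlation, or 0.116 at the preset correlation with the stricter filter). Lin28a was at 12.5 and 3.59 CPM and Pou5f1 at 3.13 and 0.983 CPM, the latter without a count in the fibroblast and early libraries and at least 39.2-fold higher than in fibroblasts (3 counts over the group as the floor). Summed over the pluripotency list, CPM was 222 and 188 in fibroblasts and 236 and 246 in late libraries.

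Hoxb13 and Hoxc12 were low in late cells too, Hoxb13 at 0.459 and 0.197 CPM (log2 fold change -7.82 ± 0.55, edgeR adjusted p = 0.0303) and Hoxc12 at 1.63 and 0.534 CPM (-6.61 ± 0.86, 0.0471). Hoxc13 (-5.27 ± 0.76, 0.0508) and Hoxa13 (-2.25 ± 0.63, 0.0905) did not pass. Of 15 posterior genes, 10 were lower and 5 higher; 2 fell and 0 rose, and 9 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00717, and adjusted p = 0.786 with an estimated correlation, or 0.0527 at the preset correlation without late replicate 2). Hoxa3 and Hoxa4 rose by 4.06 ± 0.53 and 4.51 ± 0.53, and 4 anterior genes rose adjusted over the list alone, while the anterior list was not called (adjusted p = 0.0993) except without fibroblast replicate 1 (0.0479) or late replicate 2 (0.00307). Cell cycle genes were higher for 34 of 35, with 0 called and 32 rising and 1 falling adjusted over the list alone (camera adjusted p = 7.08e-09, and adjusted p = 0.754 with an estimated correlation). The p53 list was lower (14 of 20, with Cdkn2b the 1 called gene at -4.95 ± 0.67 and 8 falling adjusted over the list alone, camera adjusted p = 0.00316, and adjusted p = 0.754 with an estimated correlation, or 0.0517 at the preset correlation without late replicate 2).

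Fibroblast and matrix genes were lower for 34 of 40 members. S100a4 fell by 3.75 on the log2 scale and Col14a1 rose by 6.34, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.32e-05, and adjusted p = 0.754 with an estimated correlation). BMP and TGF-beta targets were lower for 18 of 26, with 2 called, among them Inhba, and 4 that fell adjusted over the list alone (0.00968, and adjusted p = 0.778 with an estimated correlation, or 0.165 at the preset correlation without late replicate 2). Notch genes were higher for 12 of 15, with Notch1 called (2.05 ± 0.29) and 3 rising adjusted over the list alone (0.0190, and adjusted p = 0.754 with an estimated correlation, or 0.0623 at the preset correlation without late replicate 2). Epicardial genes were higher for 12 of 17, with Krt19, a keratin of mesothelium and simple epithelia, the 1 called and 6 rising and 1 falling adjusted over the list alone (0.0257, and adjusted p = 0.660 with an estimated correlation, or 0.0554 at the preset correlation without late replicate 2). Chromatin genes were higher for 21 of 26, with 0 called and 8 rising adjusted over the list alone (0.00277, and adjusted p = 0.649 with an estimated correlation), and skeletal muscle genes for 7 of 8, with 0 called and 2 rising adjusted over the list alone (0.0241, and adjusted p = 0.650 with an estimated correlation, or 0.0502 at the preset correlation without late replicate 2). Leukocyte markers were lower for 19 of 20 with 0 called, also over the list alone (0.00263, and adjusted p = 0.786 with an estimated correlation, or 0.208 at the preset correlation without late replicate 1), and poly(A)-free histone genes for 12 of 13 with 0 called and 9 falling adjusted over the list alone (1.95e-05, and adjusted p = 0.649 with an estimated correlation).

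Large rises in late cells under the same rule were those of Frmd5 (log2 fold change 8.39 ± 0.83), Podxl (7.88 ± 0.76), Rgs5, a regulator of G-protein signalling in pericytes (6.89 ± 0.88), Prdm6 (6.87 ± 0.47), Gata6, Col14a1 (6.34 ± 0.49) and Ildr2 (6.31 ± 0.30). Large falls were those of Cck, the cholecystokinin precursor (-8.71 ± 0.62), Htr1b (-7.71 ± 0.62), Coch (-7.09 ± 0.68), the matrix genes Thbs2 (-6.84 ± 0.83) and Col12a1 (-6.51 ± 0.80), Dkk2, a Wnt modulator (-6.27 ± 0.39), Arhgdib (-5.72 ± 0.62) and Srpx2 (-5.58 ± 0.71). Their edgeR adjusted p lay between 0.0212 and 0.0468. Hoxb13 and Hoxc12 were again left out by the limit on mean expression. In all, edgeR called 237 genes, 107 higher and 130 lower, with 5426 at an unadjusted p under 0.05. Scaling by total count gave 300, of which 60.0% were higher against 45.1%. Without fibroblast replicate 1 or fibroblast replicate 2 the count was 0 (2704 and 2319 at an unadjusted p under 0.05), and without early replicate 1, early replicate 2, late replicate 1 or late replicate 2 it was 603, 734, 1058 or 8. The balance of directions turned in these 4 fits, to 339 higher and 264 lower, 411 and 323, 809 and 249, and 8 and 0, in the same order. All 237 kept their direction in each of these fits.

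The comparison of late with early cells asks what differed between the libraries of day 7 and day 22. The edgeR test called 0 of 16688 genes; 1709 had an unadjusted p under 0.05, 1239 higher and 470 lower in late cells, limma-voom called 0 and the DESeq2 Wald test 1100 of all 31952 genes with a count, or 936 of the same 16688. Without late replicate 1, late replicate 2 alone stood for late cells, and nearly all genes that edgeR then called were higher in it. Gata4 was higher by 2.06 ± 0.52 on the log2 scale, Nkx2-5 by 3.25 ± 1.31, Tbx5 by 1.67 ± 1.11 and Mef2c by 0.87 ± 0.78, with Hand2 at -0.58 ± 0.84 and Isl1 at -1.89 ± 1.06. Their edgeR adjusted p lay between 0.377 and 0.863. Without late replicate 2 the values were 1.23 for Gata4, 0.66 for Nkx2-5, 0.05 for Tbx5, -0.34 for Mef2c and -1.05 for Isl1, and without early replicate 2 Hand2 stood at 1.37. Without late replicate 1, so with late replicate 2 alone as late cells, Gata4 stood at 2.47. Of 27 heart transcription factors 20 were higher, 6 of which rose adjusted over the list alone (camera adjusted p = 0.000132, and adjusted p = 0.571 with an estimated correlation). Mcam went from 7.53 and 6.10 CPM to 69.9 and 76.6 CPM (3.42 ± 0.33, edgeR adjusted p = 0.254), Krt8 from 0.490 and 0.663 to 156 and 46.3 CPM (7.44 ± 0.79, 0.254), and Igfbp5 from 0.223 and 0.237 to 88.1 and 183 CPM. These 3 were called without late replicate 1, where late replicate 2 alone stood for late cells.

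Interferon-stimulated genes ranked lower in late cells, with 28 of 32 lower and 3 falling adjusted over the list alone (camera adjusted p = 1.74e-10, and adjusted p = 0.571 with an estimated correlation). Ddx58, the RNA sensor RIG-I, was at 63.2 and 97.7 CPM in early and 32.7 and 21.3 CPM in late libraries, and Oas3 at 9.75 and 5.87 against 0.250 and 0.421 CPM. Smooth muscle genes ranked higher (22 of 25, 2 rising adjusted over the list alone, camera adjusted p = 7.28e-08, and adjusted p = 0.571 with an estimated correlation). Acta2, smooth muscle actin, was at 110 and 150 CPM in early and 814 and 717 CPM in late libraries. Sarcomere genes ranked higher (29 of 29, with 24 rising adjusted over the list alone). Their camera adjusted p was 8.58e-09, and 0.571 with an estimated correlation. The direction held without late replicate 2. Reads of late replicate 2 carried into late replicate 1 could add to what remained, and were not separated. Epithelial genes ranked higher too (13 of 16, 7 over the list alone, camera adjusted p = 4.15e-06, and 0.571 with an estimated correlation). Pluripotency genes did so as well (9 of 11, 6 over the list alone, camera adjusted p = 8.47e-06, and 0.571 with an estimated correlation). Posterior Hox genes were higher for 12 of 15, with 0 called and 1 rising adjusted over the list alone; the list was not called (camera adjusted p = 0.139) except upward without late replicate 2 (1.27e-08). For cell cycle genes, 32 of 35 fitted values were lower with a median of -0.28, while camera's direction on log values was upward and not called (adjusted p = 0.672). Without early replicate 2 the list ranked lower (7.30e-16) and without early replicate 1 higher (5.43e-14).

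The genes called in early and in late cells against fibroblasts overlapped. Of the 255 genes called in early cells, 148 were also called in late cells in the same direction, 79 higher and 69 lower, and 0 in the opposite direction. Independent lists of these sizes would share 1.83 genes, 0.744 higher and 1.08 lower. In 30 simulations all 6 libraries were redrawn around the fibroblast means with no gene changed, and the shared count was 0 in each. Without changed genes, calls were hardly possible, so this 0 sets no chance level for the 148 shared calls. The fold changes of all genes correlated at 0.660 across genes with a covariance of 2.97. The simulations gave a mean correlation of 0.492 and a covariance of 0.286, leaving a difference of 2.68. Both comparisons use the same 2 fibroblast libraries. These were not split, since each part would hold 1 library, and part of the excess may come from them. Of the 255 early genes, edgeR called 0 between late and early cells, and 249 had the same sign in late cells. With the replicate number as a block, 7 calls were shared. By the DESeq2 Wald test on all genes with a count, 420 early calls were also called between late and early cells and 2753 calls were shared (395 and 2876 on the filtered genes), and without late replicate 1 edgeR gave 86. The shared count was 0 without fibroblast replicate 1 or fibroblast replicate 2, 6 without early replicate 1 or late replicate 2, 454 without early replicate 2 and 251 without late replicate 1.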

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

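All tests of explanations in this part were chosen after the patterns and the values they rest on had been seen, while the list tests between late and early cells were planned.

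The direct test of late against early cells, which compares the effects of the early and the late stage over the same fibroblasts, ranked 17 lists apart at the preset correlation. With an estimated correlation 0 of the 17 were called (adjusted p of 0.571 or 0.587 for each). By fry 0 were called. Without late replicate 2, 8 of the 17 were still called in the same direction at the preset correlation. A difference between the stages is thus not shown for all of them. For the sarcomere list, reads of late replicate 2 carried into late replicate 1 could add to what remained, and were not separated. Higher in late cells were the lists for sarcomere (camera adjusted p = 8.58e-09), smooth muscle (7.28e-08), epithelium (4.15e-06), pluripotency (8.47e-06), cardiac channels (2.06e-05) and the respiratory chain (2.19e-05). Also higher were endothelium (0.000125), heart transcription factors (0.000132), fatty acid oxidation (0.000820), leukocytes (0.00139), Notch (0.00487), epicardium (0.0153), mitochondrially encoded transcripts (0.0192) and adipocytes (0.0205). Lower were interferon-stimulated genes (1.74e-10), fibroblast and matrix genes (0.00379) and anterior Hox genes (0.0185). Losing their call without late replicate 2 were cardiac channels (0.234), respiratory chain (0.279), fatty acid oxidation (0.549), leukocytes (0.999), Notch (0.165), epicardium (0.128), anterior Hox (0.677) and adipocytes (0.702). Mitochondrially encoded transcripts were then called lower (0.00963), and the respiratory chain and fatty acid oxidation lists turned downward. Without early replicate 1, epicardium (0.224), anterior Hox (0.142), Notch (0.0752), fatty acid oxidation (0.0769) and mitochondrially encoded transcripts (0.0769) missed the threshold. Without early replicate 2, the matrix list turned upward (0.142) and mitochondrially encoded transcripts missed the threshold (0.128).

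Late replicate 2 held heart muscle transcripts at levels that late replicate 1 did not approach, with Myh6 at 25360 against 25.8 CPM. Scaling or depth is argued against by the sarcomere list, whose median between these libraries lay 9.17 log2 units above that of all genes when scaled by total count, and heart muscle cells of an embryonic stage by the embryonic troponin Tnni1, which made up 0.0870% of Tnni1 and Tnni3. RNA of heart tissue is consistent with the leukocyte and adipocyte lists, whose medians were 4.79 and 4.57 log2 units higher in late replicate 2 (20 of 20 and 8 of 9 members higher), and with the erythroid list less clearly (2.25, with 3 members higher and 3 lower). The globins Hbb-bs, Hba-a1 and Hbb-bt were at 572, 311 and 74.7 CPM in late replicate 2, against 0.667, 0.167 and 0.167 in late replicate 1. In fibroblasts 19 of the 20 leukocyte members, 8 of the 9 adipocyte members and 3 of the 6 erythroid members exceeded 1 CPM. Summed over the leukocyte list, late replicate 2 was at 316 CPM, below the 351 and 1432 CPM of the fibroblast libraries. No member of the leukocyte, adipocyte or erythroid list is in another list, but that does not show that other cells of a heart lack these transcripts. The labels say that late cells were isolated as colonies. Whether that step removes leukocytes, fat cells or red cells was not tested. Mature heart muscle formed in the culture, cells that had been grafted into a heart, and a library of another sample under this label stay open, as untested.

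The same heart muscle transcripts had low counts in fibroblast replicate 2. Among 104 genes of at least 100 CPM in late replicate 2 and at least 50 times lower in late replicate 1 and the early libraries, the median level in fibroblast replicate 2 was 0.322% of that in late replicate 2. Skeletal muscle of the tail is argued against by the fast myosins Myh1, Myh2 and Myh4, which summed to 0.588 CPM beside 62.8 CPM of Myh6. Reads carried over from late replicate 2 may be a source, since 70.2% of the 104 genes lay within 2-fold of the median ratio. The share was 44.2% in fibroblast replicate 1, 53.8% in late replicate 1, and 47.1% and 27.9% in the early libraries. All 104 genes also had a count in late replicate 1. Their median level there was 0.198% of that in late replicate 2, against 0.0538% and 0.0842% in the early libraries. The 70.2% lay between the bounds set for and against carry-over (75% and 50%). By this share, carried-over reads and low expression in the culture cannot be told apart. The quartiles of the ratio in fibroblast replicate 2 were 0.256% and 0.682%. Myh6 (0.248%), Ttn (0.269%) and the globins Hbb-bs (0.298%) and Hba-a1 (0.218%) lay near the median. Lpl (2.71%), Fabp3 (2.47%) and Cd93 (8.31%) lay well above it, and were at 16.2, 12.1 and 8.56 CPM in fibroblast replicate 1.

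In early cells against fibroblasts the posterior Hox list ranked lower (10 of 15 members lower) and the anterior list higher (16 of 20 members higher), with an adjusted p of 0.892 and 0.863 with an estimated correlation. In late cells the posterior list ranked lower (10 of 15 lower, adjusted p = 0.786 with an estimated correlation, or 0.0527 at the preset correlation without late replicate 2), while the anterior list (14 of 20 higher) was not called (adjusted p = 0.0993) except without fibroblast replicate 1 (0.0479) or late replicate 2 (0.00307), and its direction turned without late replicate 1 (0.420). Scaling is argued against as the whole cause in early cells, since the medians of these lists lay 3.62 log2 units apart. Cells of another body region in the treated cultures and silencing in the vector-treated cells stay open, as untested. The design cannot separate these, because vectors and cultures changed together with the group.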

How the results depend on the processing

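Removing the mitochondrial transcripts and running DESeq2 on the filtered genes were chosen after the data were seen, and all other alternatives were planned. The planned DESeq2 test ran on all 31952 genes with a count, so that both the test and the filter differ, and its values are followed by those on the 16688 filtered genes. In early cells against fibroblasts, the 255 called genes became 0 at an adjusted p under 0.01, 514 with total count scaling, 4046 and 4201 with DESeq2, 498 with limma-voom, 2337 with no filter, 466 with the stricter filter, 1469 with only the 2 groups compared, 147 against a 1.5-fold change and 0 to 823 with a library left out. In late cells against fibroblasts, the 237 became 0 at an adjusted p under 0.01, 4722 and 4683 with DESeq2, 635 with limma-voom, 2495 with no filter, 1016 with only the 2 groups compared, 80 against a 1.5-fold change and 0 to 1058 with a library left out. In late against early cells, the 0 became 1100 and 936 with DESeq2, 276 with no filter and 0 to 602 with a library left out. The 148 shared calls became 0 at an adjusted p under 0.01, 2753 and 2876 with DESeq2 and 0 to 454 with a library left out. The 0 early calls that were called again between late and early cells became 420 and 395 with DESeq2 and 0 to 86 with a library left out. The replicate block gave 26, 9 and 0 called genes and 7 shared calls. The labels do not say that equal numbers pair libraries, and the replicate differences correlated across genes at 0.121 (fibroblast and early), 0.238 (fibroblast and late) and 0.0859 (early and late). The lists called (12, 19 and 17) became 0, 0 and 0 with an estimated correlation and 0, 8 and 0 with fry. Leaving out libraries gave 10 to 22 called lists for late cells against fibroblasts, with 10 without late replicate 2.

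Some lists turned direction when a library was left out, and their unadjusted camera p ranged widely over the libraries left out. In early cells against fibroblasts, matrix genes turned without early replicate 1 (0.981, range 7.59e-08 to 0.981). In late cells against fibroblasts, the respiratory chain (0.0584, lowest 2.06e-12) and mitochondrially encoded transcripts (0.341, lowest 2.04e-07) turned without late replicate 2. In late against early cells, matrix genes (0.114, lowest 4.43e-12) and cell cycle genes (2.35e-17, highest 0.887) turned without early replicate 2. The respiratory chain (0.189, lowest 6.06e-17), fatty acid oxidation (0.460, lowest 1.24e-12) and mitochondrially encoded transcripts (0.00279, with 4.31e-08 to 0.0993 elsewhere) turned without late replicate 2. Of 497 values of genes followed one by one, 495 had the same direction and side of the threshold with DESeq2 size factors. With the block 66 lost their call, as did 77 without either fibroblast library. No called gene changed sign in any alternative, while 55 uncalled gene values and 40 uncalled list directions did. Total count scaling moved the median of all genes by 0.17 log2 units in both comparisons with fibroblasts. Apart from the smaller number of libraries where one was left out, the cause of these differences was not tested. With 2 libraries per group, simulated changes of 4-fold were mostly not called.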

Other observations

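Some inflammatory genes differed between the early replicates, while the inflammation list as a whole did not lean to either (median log2 ratio of early replicate 2 over early replicate 1 of 0.04, with 11 of 22 members higher). Early replicate 2, which the labels call partially reprogrammed, held C3, the central complement component, at 4034 CPM against 62.7 in early replicate 1, the chemokine Cxcl12 at 6767 against 325 CPM and the acute-phase gene Saa3 at 218 against 4.28 CPM. Fibroblast and matrix genes were higher there for 32 of 40 members (median log2 ratio 1.76), and cell cycle genes for 1 of 35 (median -2.55).

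The late replicates differed in the level of the epithelial list, with a median log2 ratio of late replicate 2 over late replicate 1 of -1.20 (3 of 16 higher), and of the pluripotency list, with -1.35 (2 of 11 higher). Both Hox lists were lower in late replicate 2, with medians of -2.00 for posterior and -1.38 for anterior genes. Tcf21, a factor of epicardial derivatives, had no count in fibroblast or early libraries and was at least 156-fold higher in late cells than in fibroblasts (3 counts over the group as the floor, edgeR adjusted p = 0.0641). Kit, a receptor of stem and progenitor cells, had 1 fibroblast count and was at 9.38 and 10.9 CPM in late cells, a ratio of 655 (exact 95% counting interval 117 to 25910, edgeR adjusted p = 0.0523).

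Some lists were not called by camera in any of the 3 comparisons over all 6 libraries. Camera ranks a list as a whole, so an uncalled list can hold changed genes. In early cells against fibroblasts, edgeR called 1 Wnt target higher and 2 lower, and 1 cartilage and bone gene higher and 1 lower. Summed over the Wnt targets, CPM was 4018 and 3236 in fibroblasts, 1007 and 658 in early and 732 and 688 in late libraries. In early cells against fibroblasts, late cells against fibroblasts and late against early cells, in that order, the adjusted p was 0.479, 0.644 and 0.619 for glycolysis, 0.474, 0.825 and 0.137 for Wnt targets and 0.269, 0.585 and 0.151 for inflammation. It was 0.811, 0.585 and 0.151 for Schwann cell, melanocyte and neuron genes, 0.213, 0.585 and 0.151 for cartilage and bone, and 0.907, 0.292 and 0.0831 for the erythroid list. Leaving out a library brought some of them past the threshold in late against early cells. These were glycolysis without early replicate 2 (lower, 0.0169), Wnt targets without late replicate 2 (higher, 0.00793) and inflammation without fibroblast replicate 2 (lower, 0.0442). The Schwann cell, melanocyte and neuron list was higher without fibroblast replicate 1 (0.0238), fibroblast replicate 2 (0.0235), early replicate 2 (0.00182) or late replicate 1 (0.00520). The erythroid list was higher without fibroblast replicate 1 (0.00198), fibroblast replicate 2 (0.00190), early replicate 2 (0.0169) or late replicate 1 (1.91e-05), and in late cells against fibroblasts without fibroblast replicate 2 (0.0364) or late replicate 1 (8.70e-05). In early cells the erythroid list had a median of -1.98 while camera's direction was upward, the adipocyte list a median of -0.04 with an upward direction and the endothelial list a median of 0.10 with a downward one, all uncalled (0.907, 0.861 and 0.907).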
